A study of Arabidopsis thaliana with 30 samples.

How the data were processed

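Whole seedlings of Arabidopsis thaliana, 12 days old, were measured by messenger RNA sequencing in 30 libraries, 3 for each of 10 genotypes, per the labels. The authors deposited a table of values for 32548 genes. Per the submitters' processing notes, bcl2fastq, HISAT2 and edgeR were used with the TAIR10 build. Their versions and settings, the read counter and the annotation were not given in the sources used here.

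The deposited values are a normalised signal, not read counts. They are not whole, and in most libraries their low values cluster near multiples of what a read is worth there. This is the form of read counts adjusted to a common library size, but no header or label records that step. Column totals lay between 30914000 and 41548748. The value of a read was estimated where at least 60% of the low values (0.5 to 3.5) lay within 0.1 of a whole read, which held for 24 libraries and gave 33570000 to 40870000 reads. No pair of columns was identical, so every library counted as a replicate.

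The design fixed before the data were examined named a count test where the values were counts. As they are not, the test stated for that case was used: limma 3.58.1 in R 4.3.3 on log2(value + 1), with a term per genotype, all 30 libraries in the same fit, empirical Bayes variances with a trend and Benjamini-Hochberg adjustment at 0.05. Genes with a value of at least 10 in at least 3 libraries were tested (21868 genes, 20 residual degrees of freedom). Fold changes are on the log2(value + 1) scale, which understates the change of low genes. No fold is given against a group listed at 0, and the non-additive values of DDF1, which is at 0 in Col-0, depend on the pseudocount. Contrasts were each mutant against Col-0, each double mutant against its single mutants, ada2a against ada2b, ada2b against gcn5, ada2a against gcn5, and the non-additive effect in each double mutant.

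Gene symbols came from the reference annotation of TAIR10.1, in which all 32548 locus codes were found and 10804 had a symbol. The 24 gene lists (421 entries, of which 2 were left out because the reference gave another gene) were fixed before the data were examined and were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation. Named genes passed adjusted p below 0.05, changed at least 2-fold, had a mean of at least 2 CPM in the higher group and a symbol, and, except for the non-additive effect, had all 3 libraries of a group on a single side of the other group. The 10 largest rises and 10 largest falls were taken in gcn5, ada2b, ada2a and spc, and 5 of each in every other contrast, with the mutated genes. From each described list came up to 4 members with the smallest adjusted p and up to 2 with the largest fold that did not pass. TCH4 in gcn5, ada2b and eaf6, and the genes of the patterns in the closing section, were chosen after their values were seen. Genes with near-identical copies and overlapping genes share reads to an extent that depends on the authors' counting, so members of families such as LHCB are uncertain one by one.

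The gene test was checked on simulated data with the spread of the real libraries for the contrast of gcn5 with Col-0 (21868 genes). It recovered 38.2% of genes changed by 0.5 on the log2 scale, 72.7% at 1 and 90.9% at 2, and 4 unchanged genes were called (2.9% of the calls). A list shifted by 0.5 was called and 0 other lists were, but the simulated genes vary independently, so this does not test camera on correlated genes. Chance correlation and overlap between contrasts that share the Col-0 libraries came from 50 simulations of unchanged groups. Alternatives were size factors from median ratios, no filter on low values, a fit of only the groups compared, the replicate number as a block, leaving out each library, a 2-fold minimum and an estimated correlation. Division by column totals, a pseudocount of 16 and the mean of the other mutants as reference were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.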

Results

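Messenger RNA of 12-day-old whole Arabidopsis thaliana seedlings was sequenced in 30 libraries. They came from 10 genotypes with 3 libraries each. GCN5 is a histone acetyltransferase that works in multi-subunit complexes, and the series compares the wild type Col-0 with 9 mutants of subunits of such complexes. The 7 single mutants are gcn5, ada2b, ada2a, spc, ing1, sdrl and eaf6, and the double mutants are ada2aspc and spcing1. The deposited values are a normalised signal per gene. Column totals lay between 30914000 and 41548748, and the lowest of the group means were 31460173 in ada2b and 32889855 in gcn5, against 37742537 in Col-0. For 24 libraries the low values allowed an estimate of the reads counted, which lay between 33570000 and 40870000. Pearson's r across genes between libraries of a genotype lay between 0.979 and 0.984. Between libraries of different genotypes it lay between 0.8995 and 0.9817, so some of these were as close as replicates. The labels do not say whether the libraries of a genotype came from separate growths, so the p-values measure the spread between these libraries, which may be technical. Errors of means are SD with n = 3, and errors of log2 fold changes are SE.

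The transcript of each mutated gene that the reference names was compared with Col-0 first. ADA2A (AT3G07740, TAIR10.1 chromosome 3, 2469783 to 2473095, minus strand) was at 589 ± 36.4 in Col-0, 14.8 ± 5.90 in ada2a and 6.44 ± 2.86 in ada2aspc, which is 2.5% and 1.1% of Col-0. ING1 (AT3G24010, chromosome 3, 8675905 to 8678286, minus strand) was at 707 ± 30 in Col-0, 159 ± 24.2 in ing1 and 146 ± 37.0 in spcing1. EAF6 (AT4G14385, chromosome 4, 8286745 to 8288952, minus strand) was at 825 ± 9.25 in Col-0 and 118 ± 23.5 in eaf6. GCN5 (AT3G54610, chromosome 3, 20213406 to 20217653, plus strand) was at 49.2% of Col-0 in gcn5 (log2 fold change -1.03 ± 0.12, adjusted p = 2.1e-08). ADA2B (AT4G16420, chromosome 4, 9262621 to 9266157, minus strand) was at 72.3% of Col-0 in ada2b (log2 fold change -0.47 ± 0.07, adjusted p = 4.2e-06). ADA2B also passed as lower than Col-0 in mutants not named for it, at 86.3% in gcn5, 83% in spc, 84% in ing1, 84.5% in eaf6 and 87.1% in spcing1, and it was lower in ada2b than in gcn5 (-0.26 ± 0.07, adjusted p = 0.00595). GCN5 passed as lower in ing1 (80.6%) and spcing1 (78%) too, and as higher in ada2b (128.3%, adjusted p = 0.01). The label of ada2b was thus checked only by a small difference. These are values over whole genes, so they do not show which part of a transcript remained. The loci of SPC and SDRL were not identified here, and the labels of spc and sdrl were not checked in this way.

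**Figure D1:**
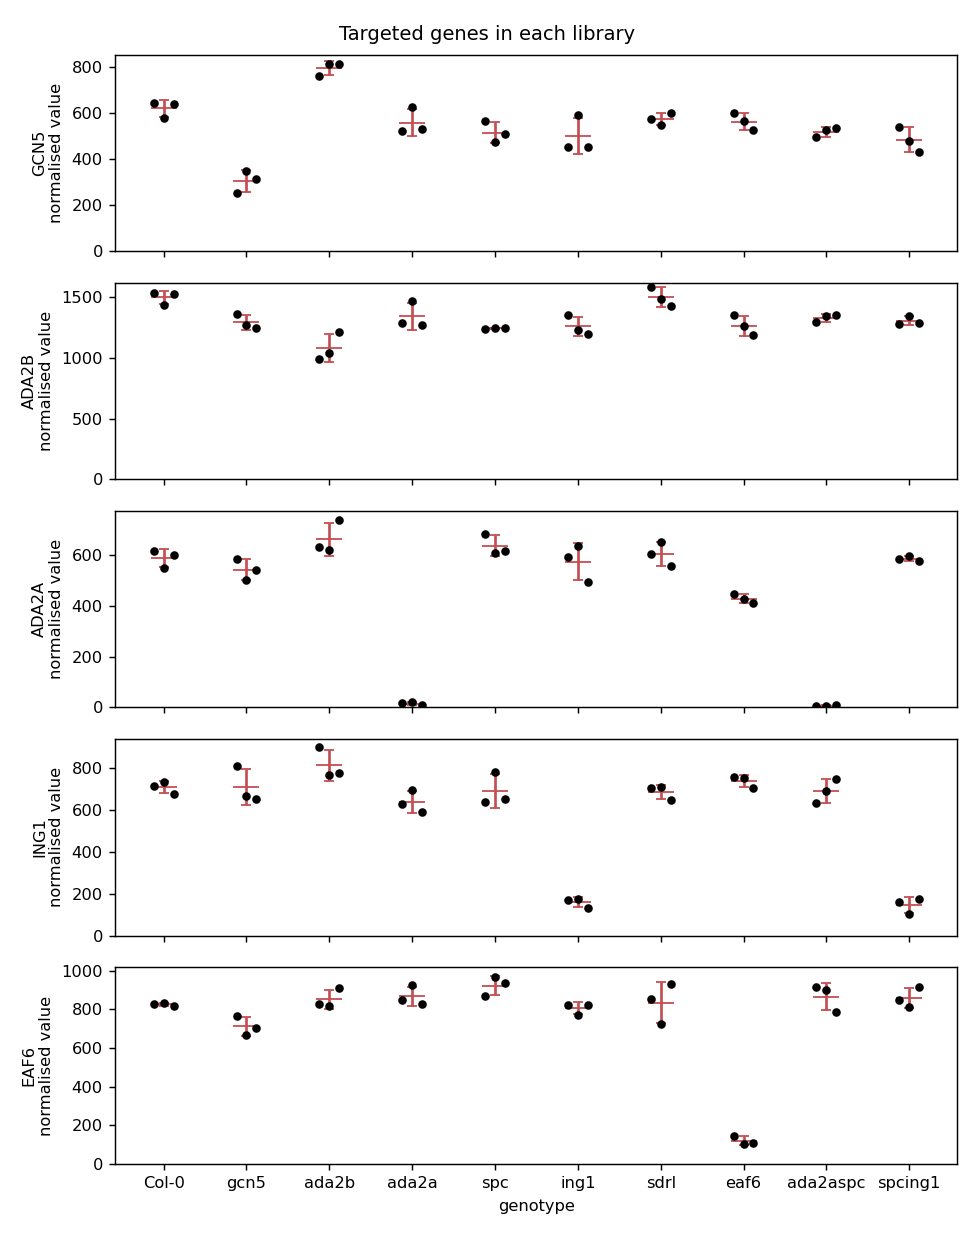
Normalised value (linear axis from 0) of GCN5, ADA2B, ADA2A, ING1 and EAF6 in each of the 30 libraries by genotype; points are libraries, and red bars show the mean ± SD of 3 libraries. ADA2A lies between 8.32 and 19.9 in the ada2a libraries and between 548.5 and 618.7 in the Col-0 libraries.

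Seedlings of gcn5 had lower transcripts of the photosynthetic apparatus and of iron uptake, and higher transcripts of phosphate starvation and root hairs. All 24 tested photosynthesis genes, a list for shoot green tissue, fell, with a median log2 fold change of -1.24. Values of whole seedlings, here and in the other mutants, do not separate expression per cell from the share of shoot and root. Among them were the chlorophyll-binding proteins LHCB2.1 (-2.63 ± 0.11, adjusted p = 6.4e-17) and LHCB1.1 (-2.93 ± 0.13, adjusted p = 2.5e-16). PORA, a protochlorophyllide oxidoreductase, went from 1192 ± 236 to 27.7 ± 16.7, and the arginase gene ARGAH2 from 1226 ± 244 to 24.1 ± 3.37. Of 18 iron deficiency genes 14 fell and 1 rose, including the iron transporter IRT1 (-2.49 ± 0.17) and the ferric reductase FRO2 (-2.07 ± 0.20). Of 25 auxin response genes 17 fell and 2 rose, and the auxin-inducible IAA29 fell by 2.47 on the log2 scale. Of 16 abscisic acid and drought genes 11 fell and 0 rose, with RD29B at -4.30 ± 0.45. Phosphate starvation genes rose in 13 of 17 cases, for example SPX2 (0.85 ± 0.09), and 7 of 10 root hair genes rose, for example the expansin gene EXPA7 (1.18 ± 0.19). The largest rises in named genes were those of DIN2, a dark-inducible glycosyl hydrolase (20.7 ± 15.3 to 501 ± 73.6), and ARI13 (2.35 ± 1.34 to 77.7 ± 21.4). In all, 9333 of 21868 tested genes changed, 3973 up and 5360 down, and 751 rose and 1498 fell at least 2-fold. With values divided by column totals, an alternative chosen after seeing the data, the median of all genes moved to 0.173 the calls split into 7685 up and 3521 down, and those of at least 2-fold into 1182 up and 1113 down. With a pseudocount of 16, also chosen then, 493 rose at least 2-fold. By camera the photosynthesis list was lower than other genes (adjusted p = 4.7e-21, and adjusted p = 0.0467 with an estimated correlation). The calls for iron deficiency, auxin response, abscisic acid and phosphate starvation were lost there, with adjusted p = 0.292, 0.119, 0.351 and 0.492, and for root hair with adjusted p = 0.351.

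Seedlings of ada2b had lower transcripts of photosynthesis, auxin and cytokinin genes. Photosynthesis genes fell in 23 of 24 cases (median log2 fold change -1.46), with LHCB2.1 at -4.49 ± 0.11 and LHCB3 at -3.11 ± 0.09, while the Rubisco subunit gene RBCS1B did not pass (-0.22 ± 0.10, adjusted p = 0.065). ARGAH2 went from 1226 ± 244 to 1.87 ± 3.23 and PORA from 1192 ± 236 to 6.67 ± 0.45. The nicotianamine synthase gene NAS2 was at 165 ± 94.2 in Col-0 and listed at 0 in all ada2b libraries. Auxin response genes fell in 19 of 25 cases and rose in 3, with IAA29 at -5.34 ± 0.23 and IAA6 at -4.91 ± 0.27. Of 15 genes of auxin synthesis and transport 13 fell and 1 rose, including the efflux carriers PIN7 (-1.16 ± 0.06) and PIN4 (-1.40 ± 0.07). Of 16 cytokinin genes 11 fell and 0 rose, among them the response regulator ARR9 (-1.59 ± 0.09) and the cytokinin oxidase CKX4 (-2.67 ± 0.15). The floral repressor FLC went from 8.95 ± 2.73 to 107 ± 23.8, and the floral promoter SOC1 fell by 1.73 on the log2 scale. DIN2 went from 20.7 ± 15.3 to 1214 ± 6.02, and the transcription factor genes WRKY40 (3.39 ± 0.25) and ZAT10 (3.56 ± 0.24) rose. In all, 11288 genes changed, 5142 up and 6146 down, and 678 rose and 2827 fell at least 2-fold. With column totals the median of all genes was 0.273 and the calls were 10093 up and 4382 down, of which 1343 and 2169 were at least 2-fold. The lists of photosynthesis, auxin response, auxin synthesis and transport, and cytokinin passed camera also with an estimated correlation (adjusted p = 0.0199, 0.012, 0.0131 and 0.0312).

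The direct contrast of ada2b with gcn5 tested the difference between these mutants. Of 16 cytokinin genes 12 were lower in ada2b and 0 higher, with CKX4 at -1.54 ± 0.15 (adjusted p = 0.0239 for the list with an estimated correlation). Of 25 auxin response genes 16 were lower and 3 higher, with IAA6 at -2.99 ± 0.27 (adjusted p = 0.0239 for the list with an estimated correlation). The phosphatase gene PAP5 was at 144 ± 86.2 in gcn5 and 0.307 ± 0.531 in ada2b. The biotin ligase gene HCS2 was at 0.515 ± 0.892 in gcn5 and 167 ± 40.1 in ada2b. In all, 9214 genes differed, 498 at least 2-fold higher and 1591 at least 2-fold lower in ada2b. Dividing by column totals changed the split of all calls from 4278 higher and 4936 lower to 5525 higher and 4226 lower, and a pseudocount of 16 left 849 genes at least 2-fold lower.

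In ada2a more listed genes of immunity, jasmonate and hypoxia rose than fell. Among the largest rises of named genes, TCH4, a touch-induced xyloglucan endotransglucosylase, went from 593 ± 42.9 to 27660 ± 4620 and the calmodulin-like TCH3 from 447 ± 89.3 to 9177 ± 1120. WRKY40 went from 100.4 ± 29.4 to 2671 ± 233 and the ethylene response factor gene ERF6 from 151 ± 34.9 to 3632 ± 388. Of 23 salicylic acid and immunity genes 13 rose and 1 fell, including WRKY33 (3.55 ± 0.20) and SARD1 (3.64 ± 0.32). Of 21 jasmonate genes 11 rose and 4 fell, with the repressor gene JAZ1 at 1.95 ± 0.15. All 7 hypoxia genes rose, with LBD41 at 0.98 ± 0.11. The clock genes CCA1 (1462 ± 497 to 224 ± 8.39) and PRR9 (588 ± 109 to 120.5 ± 36.8) fell, and so did the cold regulator CBF3 (-2.29 ± 0.36). These changes are not particular to ada2a. CCA1 and PRR9 fell in all 9 mutants. TCH4, TCH3, WRKY40 and ERF6 rose at least 4-fold in each of the 7 mutants other than gcn5 and ada2b. Handling and harvest hour are not in the labels and are taken up under the other observations. The defence gene PR2, a glucanase, fell by 3.62 on the log2 scale (939 ± 865 in Col-0), a call lost without Col-0 replicate 3 (adjusted p = 0.064), and the aminotransferase gene TAT3 fell from 321 ± 297 to 21.4 ± 3.81. In all, 6492 genes changed, 3312 up and 3180 down, and 900 rose and 314 fell at least 2-fold. Dividing by column totals moved the median of all genes to -0.115 and the calls to 2627 up and 4902 down, and a pseudocount of 16 left 174 falls of at least 2-fold. The camera calls for immunity, jasmonate and hypoxia were lost with an estimated correlation (adjusted p = 0.486 for each).

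In spc TCH4 was at 31560 ± 2260, DREB26 at 3412 ± 402 against 113 ± 14.6 in Col-0, and the ethylene response factor gene ERF104 rose by 4.40 ± 0.21 on the log2 scale. The transcription factor gene DDF1 was listed at 0 in the Col-0 libraries and at 99.3 ± 15.3 in spc. TCH4, DREB26, ERF104 and DDF1 passed as raised in each of the 7 mutants other than gcn5 and ada2b. All 7 hypoxia genes and 13 of 23 immunity genes rose. Of 14 glucosinolate genes 7 fell and 0 rose, with the regulator MYB29 at -1.26 ± 0.21. Of 24 photosynthesis genes 13 fell and 0 rose, with a median log2 fold change of -0.27. CBF3 went from 499 ± 12.3 to 56.2 ± 12.4 and the aminopeptidase gene MAP1B from 740 ± 28.4 to 127 ± 9.06. In all, 8729 genes changed, 4431 up and 4298 down, and 1197 rose and 577 fell at least 2-fold. With column totals the median of all genes was -0.102, and 3425 genes were called up and 5843 down. A pseudocount of 16 left 368 falls of at least 2-fold. No list passed camera with an estimated correlation (adjusted p = 0.55 for hypoxia, immunity, glucosinolate and photosynthesis).

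In ing1 and sdrl TCH4 reached 24140 ± 3400 and 40190 ± 3040, and EXO, a cell expansion gene, 15910 ± 1450 and 25050 ± 685 against 560.5 ± 66.6 in Col-0. Both genes rose at least 4-fold in each of the 7 mutants other than gcn5 and ada2b. CBF3 was at 31.4 ± 10.2 in ing1 and 29.2 ± 13.7 in sdrl. Of 18 iron deficiency genes 12 fell and 0 rose in ing1, with the peptide genes IMA3 (-2.19 ± 0.31) and IMA1 (-1.80 ± 0.28), and that call was lost with an estimated correlation (adjusted p = 0.49). Of 15 brassinosteroid genes 9 rose and 0 fell in sdrl, including the transcription factor gene BZR1 (0.94 ± 0.09) and the synthesis gene DWF4 (0.76 ± 0.09). Of 11 heat shock genes 6 rose and 0 fell in sdrl, with HSFA3 at 1.88 ± 0.16. Both lists also passed in sdrl with an estimated correlation (adjusted p = 0.0112 and 0.0455). In all, 7799 genes changed in ing1, with 1006 rising and 400 falling at least 2-fold, and 7838 changed in sdrl, with 990 and 480. With the mean of the other 8 mutants as reference in place of Col-0, added after seeing the data, the counts of changed genes were 2925 and 4221, and those of at least 2-fold rises were 132 and 162. A pseudocount of 16 left 258 and 280 falls of at least 2-fold. Dividing by column totals moved the calls from 3819 up and 3980 down to 3182 up and 5166 down in ing1, and from 3713 up and 4125 down to 3034 up and 5567 down in sdrl. Size factors turned these splits to 4026 and 3688 in ing1 and 4018 and 3675 in sdrl.

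In eaf6 18 of 23 immunity genes rose and 0 fell, among them WRKY70 (1.84 ± 0.19) and PAD4 (0.91 ± 0.12). PR1, a marker of salicylic acid responses, was at 2974 ± 1480 against 172 ± 151, and its adjusted p of 0.0114 became 0.105 without Col-0 replicate 1. TCH4, chosen here after its value was seen, was at 16520. The carotenoid cleavage dioxygenase gene CCD7 went from 2.04 ± 1.01 to 118 ± 37.8. Flavonoid and anthocyanin genes rose in 9 of 15 cases and fell in 1, with the dihydroflavonol reductase gene DFR at 2.40 ± 0.47. Of 17 phosphate starvation genes 11 rose and 0 fell. Of 16 abscisic acid and drought genes 13 fell and 1 rose, with the phosphatase gene HAI2 at -3.50 ± 0.32. Photosynthesis genes fell in 21 of 24 cases (median log2 fold change -0.50). In all, 11154 genes changed, 5500 up and 5654 down, and 1985 rose and 695 fell at least 2-fold. The split of all calls was 5906 up and 5066 down with column totals and 5855 up and 5205 down with size factors. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.231 for immunity, abscisic acid and photosynthesis, 0.408 for flavonoids and 0.545 for phosphate starvation).

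**Figure D2:**
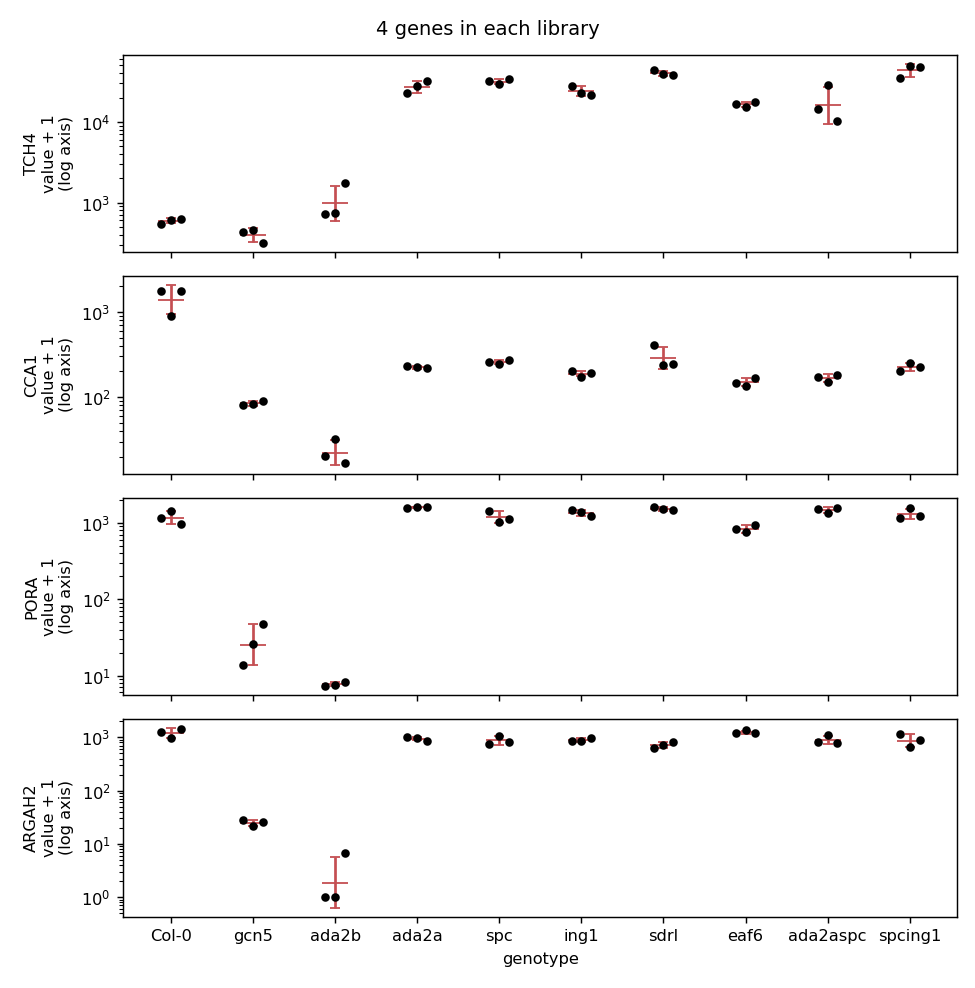
Value + 1 (log axis) of TCH4, CCA1, PORA and ARGAH2 in each of the 30 libraries by genotype; points are libraries, and red bars show the mean ± SD of log2(value + 1) over 3 libraries. CCA1 lies between 888 and 1756 in the Col-0 libraries and is lower in every mutant library, while ARGAH2 falls below the other genotypes in gcn5 (20.4 to 27.1) and ada2b (0 to 5.60).

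**Figure D3:**
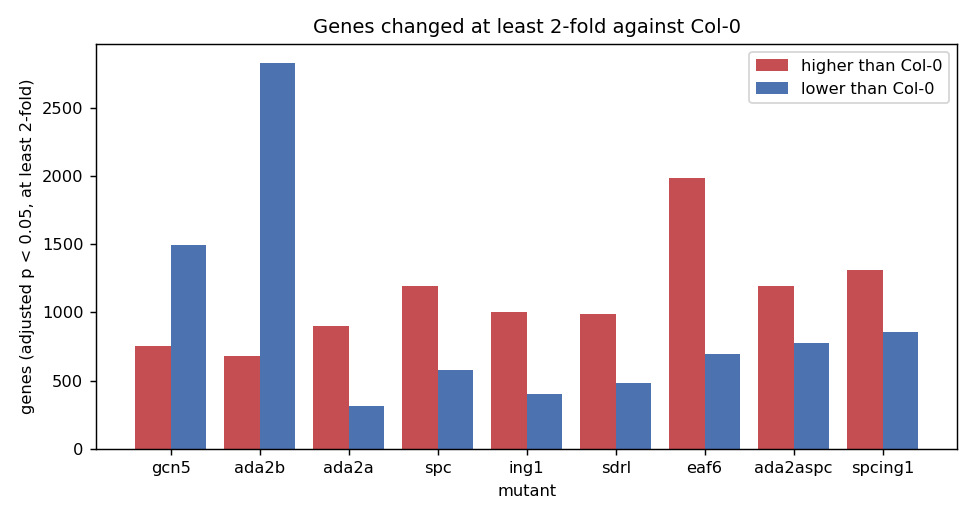
Number of genes (bars from 0) with adjusted p below 0.05 and at least 2-fold higher (red) or lower (blue) in each mutant than in Col-0, 3 libraries each. Falls outnumber rises in gcn5 (1498 against 751) and ada2b (2827 against 678), and rises outnumber falls in the other 7 mutants. With column totals these directions turned in gcn5 (1182 rises, 1113 falls) and spcing1 (1123 rises, 1127 falls).

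ADA2A and ADA2B are related adaptor proteins, and their mutants were compared directly. All 24 photosynthesis genes were higher in ada2a than in ada2b, with LHCB2.1 at 3.84 ± 0.11 (adjusted p = 0.0519 for the list with an estimated correlation). Auxin response genes were higher in ada2a in 19 of 25 cases and lower in 3, with IAA6 at 6.20 ± 0.27 (adjusted p = 0.0242 for the list with an estimated correlation). ARGAH2 was at 951 ± 77.9 in ada2a against 1.87 ± 3.23 in ada2b, and DIN2 at 19.0 ± 9.70 against 1214 ± 6.02. In all, 13932 genes differed, 3636 at least 2-fold higher and 1241 at least 2-fold lower in ada2a. Against gcn5, ada2a differed in 11374 genes, with 2213 and 992 at least 2-fold. TCH4 was at 27660 ± 4620 in ada2a and 400.2 ± 78.3 in gcn5, and all 24 photosynthesis genes were higher in ada2a (adjusted p = 0.15 for the list with an estimated correlation). Dividing by column totals moved the median of all genes to -0.329 against ada2b and -0.279 against gcn5. It changed the split from 7322 higher and 6610 lower to 4976 and 11065 against ada2b, and from 6255 and 5119 to 4021 and 10046 against gcn5. The 2-fold splits turned too, to 2571 higher and 2832 lower against ada2b and to 1561 and 1856 against gcn5.

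The ada2aspc double mutant was compared with each single mutant. The cell wall genes XTH15 (2484 ± 15.1 against 485.5 ± 154 in ada2a and 662 ± 181 in spc) and EXPA16 (774 ± 64.5 against 168 ± 14.3 and 192 ± 44.4) were higher in the double mutant. ACS6, an ethylene synthesis gene, was at 570.1 ± 205 against 4285 ± 314 in ada2a and 4358 ± 185 in spc. CBF2 was at 13.6 ± 5.08 against 187 ± 93.5 and 140 ± 63.9. Of 15 cold response genes 7 were lower than in ada2a and 8 lower than in spc, and 0 were higher in either contrast (adjusted p = 0.0265 and 0.0268 with an estimated correlation). Of 15 auxin synthesis and transport genes 8 were higher and 1 lower than in spc, with the auxin synthesis gene YUC8 at 1.78 ± 0.19 (adjusted p = 0.00473 for the list with an estimated correlation). In all, 3215 genes differed from ada2a (98 at least 2-fold higher and 227 lower) and 2604 from spc (86 and 217). The count of 98 was 150 without ada2a replicate 3 and 62 with a pseudocount of 16, which also took 86 to 53. Against Col-0, 9716 genes changed in ada2aspc, 1194 rising and 778 falling at least 2-fold. Dividing by column totals moved the calls against Col-0 from 4738 up and 4978 down to 3824 up and 6245 down, and those of at least 2-fold to 1018 and 979. Size factors turned the split to 5039 up and 4701 down.

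In the spcing1 double mutant heat shock genes were higher than in spc in 6 of 11 cases and lower in 0, with HSFA2 at 121 ± 17.3 against 37.8 ± 16.7 (adjusted p = 0.00164 for the list with an estimated correlation). Of 15 cold response genes 9 were lower than in spc and 0 higher, with CBF1 at -2.04 ± 0.32 (adjusted p = 0.00886 for the list with an estimated correlation). XTH33 was at 601 ± 126 against 152 ± 12.0 in spc and 223 ± 19.9 in ing1. ACS6 was at 1009 ± 92.5 against 4358 ± 185 in spc. In all, 1543 genes differed from spc (60 at least 2-fold higher and 108 lower) and 617 from ing1. Of these, 20 were at least 2-fold higher and 43 lower than in ing1, and this turned to 25 and 10 with only the groups compared and to 24 and 13 with a pseudocount of 16. The count of 43 was 18 without ing1 replicate 2, 19 without ing1 replicate 3, 21 without spcing1 replicate 2 and 69 without spcing1 replicate 1. The count of 20 was 12 without ing1 replicate 3 and 10 without spcing1 replicate 2. The count against ing1 was 228 without spcing1 replicate 2, 342 without spcing1 replicate 3, 252 without ing1 replicate 2 and 233 without ing1 replicate 3. The split of its calls went from 390 higher and 227 lower to 297 and 311 with column totals and to 363 and 111 with only the groups compared. The split against spc went from 789 higher and 754 lower to 716 and 870 with column totals. Its lower calls were 453 without spc replicate 2 and 485 without spc replicate 3. Against Col-0, 9815 genes changed in spcing1, 1309 rising and 854 falling at least 2-fold, and column totals moved the calls from 4581 up and 5234 down to 3584 up and 7022 down. Size factors turned that split to 4980 up and 4679 down. With column totals the 2-fold split turned to 1123 up and 1127 down, and a pseudocount of 16 left 533 falls of at least 2-fold.

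A non-additive effect is the double mutant's change from Col-0 less the sum of both single mutants' changes. DIC2, a mitochondrial carrier gene, had -8.49 ± 0.42 in ada2aspc and -5.65 ± 0.42 in spcing1, and SZF1 had -7.11 ± 0.30 in ada2aspc. The effect was positive for CCA1 (2.71 ± 0.31) and PRR9 (2.72 ± 0.38) in spcing1. Both genes fell in all 9 mutants. CCA1 was at 1462 in Col-0, 255 in spc, 187 in ing1 and 225 in spcing1, and PRR9 at 588, 93.2, 59.6 and 63.0. The fall was thus of like size in the single and double mutants, which alone gives a positive value. A harvest of Col-0 at another hour cannot be told apart from genotype here. In all, 4069 genes had such an effect in ada2aspc, 349 at least 2-fold positive and 976 negative, and 4075 in spcing1, 307 and 883. The split in ada2aspc changed with column totals from 1697 positive and 2372 negative to 2751 and 1977, and in spcing1 from 1739 and 2336 to 2193 and 2021. Of 100 splits of the libraries, the real one counted among them, 5 gave as many genes for ada2aspc and 3 for spcing1. Both counts depend on which splits are drawn. The splits mix libraries of genotypes that differ, so they do not test whether effects add up.

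The changes of different mutants were correlated across the 21868 genes, which are not independent replicates. All contrasts share the Col-0 libraries, and unchanged groups simulated against shared controls gave r = 0.50 and a covariance of 0.048. Such groups have no effects, so 0.50 is not the r to expect by chance between mutants that have them. The covariances can be set against 0.048. The r of ada2a was 0.851 with spc, 0.829 with ing1, 0.80 with sdrl and 0.595 with eaf6, with covariances of 0.395, 0.347, 0.333 and 0.309. The r of spc with ing1 was 0.849 (covariance 0.401) and that of gcn5 with ada2b 0.673 (covariance 0.516). The r of ada2a with gcn5 was 0.216 (covariance 0.109) and with ada2b 0.083 (covariance 0.052). The r of ada2aspc was 0.267 with gcn5 (covariance 0.149) and 0.040 with ada2b (covariance 0.028). For ada2a and spc 3094 genes rose and 2637 fell in both, where independent lists give 671 and 625, and 1 went opposite ways. For gcn5 and ada2b 2253 rose and 3744 fell in both, where independent lists give 934 and 1506. For ada2a and ada2b 978 rose and 824 fell in both, where independent lists give 779 and 894, and 2029 went opposite ways. The simulated overlaps were 0, which the adjusted p nearly fixes for unchanged groups. Part of each excess may come from the shared controls, which were not split, as 3 libraries do not give 2 for each contrast.

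**Figure D4:**
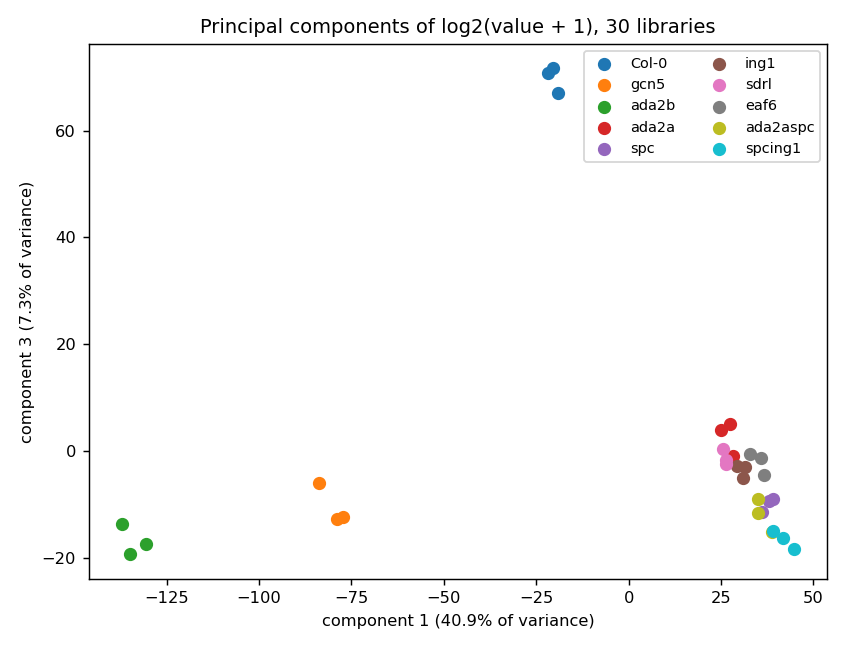
Principal components 1 and 3 (percent of variance on each axis) of log2(value + 1) over 21868 genes; each point is a library and each colour a genotype. The Col-0 libraries lie between 67.1 and 71.7 on component 3, where no mutant library is above 5.1, and ada2b and gcn5 lie apart on component 1.

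Across the 24 lists, the largest median falls were those of iron deficiency in ada2b (-1.94) and gcn5 (-1.62), and the largest median rise was that of heat shock in sdrl (1.45). Of 18 iron deficiency genes 13 fell and 1 rose in ada2b, and the list's call was lost with an estimated correlation in ada2b (adjusted p = 0.177) and gcn5 (adjusted p = 0.292). The camera calls with the preset correlation numbered 9 in gcn5, 11 in ada2b, 3 in ada2a, 6 in spc, 9 in ing1, 6 in sdrl, 9 in eaf6, 8 in ada2aspc and 9 in spcing1. They numbered 1, 4, 0, 0, 0, 2, 0, 1 and 1 with an estimated correlation. The calls in ada2a numbered 5 without Col-0 replicate 1 or ada2a replicate 1 and 6 without Col-0 replicate 2 or ada2a replicate 2, and those in sdrl 10 without sdrl replicate 1. For 8 of the 9 mutants against Col-0, all but spcing1, other splits of the same libraries gave as many list calls. The other contrasts were not split for their lists. The statements on gene groups thus rest on counts of members called one by one, which do not test a group. Of all tested genes 42.7% passed in gcn5, 51.6% in ada2b, 29.7% in ada2a and 39.9% in spc. In ing1, sdrl and eaf6 the shares were 35.7%, 35.8% and 51%. Between mutants they ran from 2.8% (spcing1 against ing1) to 63.7% (ada2a against ada2b). Member counts are to be read against these shares. Adjusted over the list alone, 24 of 24 photosynthesis genes fell in gcn5, 24 of 24 in ada2b and 22 of 24 in eaf6.

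**Figure D5:**
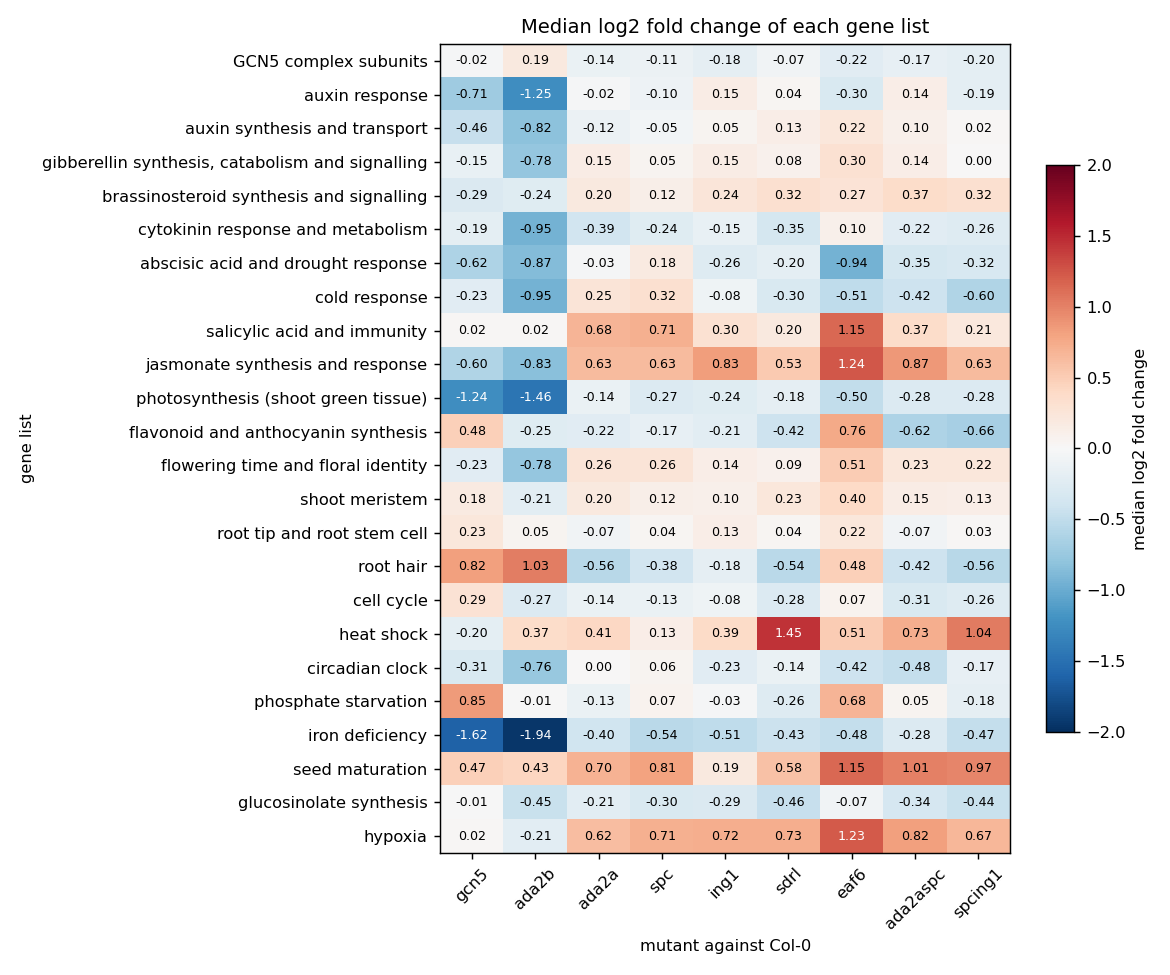
Median log2 fold change against Col-0 (number and colour in each cell) of 24 gene lists (rows) in 9 mutants (columns). Photosynthesis is lowest in gcn5 (-1.24) and ada2b (-1.46), and hypoxia is highest in eaf6 (1.23).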

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

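The tests of the explanations below were chosen after the results were seen, and the splits of the libraries were planned before. A non-additive effect, which is a difference between the effect of a mutation in Col-0 and in another mutant, passed the threshold in 4069 genes for ada2aspc and 4075 for spcing1. In ada2aspc the named genes were TAT3 (5.86), ASG8 (2.78), PRE1 (2.52), IAA29 (2.45), YUC2 (2.23), DIC2 (-8.49), DDF1 (-7.64), CML37 (-7.46), SZF1 (-7.11) and CYP707A3 (-6.93), on the log2 scale. In spcing1 they were PCR1 (6.24), TAT3 (3.87), PRR9 (2.72), CCA1 (2.71), CIPK20 (2.45), DDF1 (-7.57), DIC2 (-5.65), TCH4 (-4.87), CML37 (-4.84) and RAS1 (-4.52). DDF1 is listed at 0 in Col-0, so its values depend on the pseudocount and are no measure of a fold. TAT3 and PCR1 varied widely between the Col-0 libraries (SD 297 and 219). CCA1 and PRR9 fell in all 9 mutants, so their values may come from Col-0 alone, which was not tested.

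Of 100 splits of the 12 libraries, the real one counted among them, 5 gave at least 4069 genes for ada2aspc (highest other split 4768). The 95% interval of that share, 1.64% to 11.3%, treats the real split as if drawn and is only rough. The count depends on which 100 splits are drawn, and another draw fell under 5%. For spcing1 3 of 100 did, the real split again counted (0.623% to 8.52%, highest other split 6524). That share is under 5%, but its rough interval reaches above, so the draws do not settle it. The median count of the other splits was 0 in both double mutants. Each split moves libraries between genotypes that differ in many genes, so it can carry those differences into the contrast. It asks whether the genotypes differ at all, not whether their effects add up. Neither share thus decides whether chance gave the non-additive effects, and chance is not excluded.

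In both double mutants 2526 genes had a non-additive effect of the same sign. Both effects are computed with the same Col-0 and spc libraries, so they are not independent. The overlap to expect from that sharing was not computed. An offset of the Col-0 libraries from every mutant is not settled by the sign. The mutants gcn5 and ada2b share those libraries. The opposite sign was found in 0.646 of these genes in gcn5 and 0.508 in ada2b, against 0.813 from simulated noise alone. The simulation gave gcn5 and ada2b no effects of their own, which would move these shares. The median change opposite to the effect was 0.14 in gcn5 and 0.01 in ada2b (upper quartiles 0.47 and 0.46). The effect itself had a median size of 0.79. These sizes argue against an offset as the whole cause, unless effects of gcn5 and ada2b themselves cancelled it, which was not tested. That both mutations change the same genes and the second adds little cannot be told apart from chance by the sign. All single mutants were opposite in 0.981 of the genes, but noise alone gave 0.873. The noise genes were taken by rank, as many as observed, and not by adjusted p. The value of 0.873 is thus not the share for called genes. The median change of the 2526 genes opposite to the effect was 0.69 in ada2a, 0.83 in spc and 0.70 in ing1, close in size to the effect, but the effect is computed from those changes, so this stays open too. Over all tested genes, spcing1 differed from spc in 1543 genes and from ing1 in 617. The count for ada2aspc was 3215 against ada2a and 2604 against spc. Against Col-0, ada2a, spc and ing1 differed in 6492, 8729 and 7799. Each second mutation thus came with fewer calls than the same mutation in Col-0. An offset of the Col-0 libraries would give that too. Of the 115 genes raised in 7 mutants described under the other observations, 108 are among the 2526. What stays open there stays open for these 108 genes, and the rest of the 2526 were not tested for it.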

How the results depend on the processing

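Column totals, a pseudocount of 16 and the other mutants as reference were chosen after seeing the data. With size factors, no filter, a pseudocount of 16 or only the groups compared, every total of genes with adjusted p below 0.05 stayed within 1.5 times, but for spcing1 against ing1 the lower calls went from 227 to 111 with only the groups compared. Which direction had more calls turned with size factors in ing1, sdrl, eaf6, ada2aspc and spcing1. In eaf6 it also turned with no filter (5634 and 5619) and with only the groups compared (5767 and 5759). Counts of at least 2-fold moved more. Those that a pseudocount of 16, column totals or only the groups compared moved by over 1.5 times or turned are given beside each result. Of 2748 checks of named genes 2718 were the same and 30 lost the threshold, mostly in spcing1 against ing1; none turned. The tests that need counts were not run, as the values are not counts. Where values moved, the cause was not tested, with the exception of column totals and the 2-fold minimum. Dividing by column totals shifts nearly all genes of a library alike, by an amount set by its total. That shift was upward in gcn5 and ada2b, whose totals were the lowest. Which scaling is nearer the truth was not tested. A 2-fold minimum only removes genes. It left 2249 genes in gcn5, 3505 in ada2b, 1214 in ada2a, 1774 in spc, 1406 in ing1, 1470 in sdrl, 2680 in eaf6, 1972 in ada2aspc and 2163 in spcing1. It left 325 and 303 for ada2aspc against ada2a and spc, 168 and 63 for spcing1 against spc and ing1, 4877 for ada2a against ada2b, 2089 for ada2b against gcn5, 3205 for ada2a against gcn5, and 1325 and 1190 non-additive.

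With the other mutants as reference the counts were 2925 in ing1, 4221 in sdrl and 5662 in ada2aspc, and 12545 in gcn5 and 15629 in ada2b. Rises of at least 2-fold were then 1140 in ada2b and from 132 (ing1) to 412 (spc) in the mutants other than gcn5, ada2b and eaf6, and falls 162 in eaf6 and from 42 (ing1) to 220 (spcing1) in the same mutants. The list calls were 10 in ada2a and 11 in sdrl. The correlations were then 0.763 for gcn5 and ada2b, -0.260 for gcn5 and ada2a, -0.047 for ada2a and ada2b, 0.609, 0.505, 0.472 and 0.150 for ada2a with spc, ing1, sdrl and eaf6, 0.560 for spc and ing1, and -0.278 and -0.323 for ada2aspc with gcn5 and ada2b. Unchanged mutants, each simulated against the mean of all the others, gave r = -0.125. That is no baseline for the r above, and how the reference itself moves them was not tested. With no filter r was 0.792, 0.770 and 0.748 for ada2a with spc, ing1 and sdrl and 0.795 for spc and ing1. Column totals gave 5 list calls in ada2a. An estimated correlation left 1 list in gcn5, 4 in ada2b, 0 in ada2a, 0 in spc, 0 in ing1, 2 in sdrl, 0 in eaf6, 1 in ada2aspc and 1 in spcing1.

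Leaving out single libraries gave 228 (without spcing1 replicate 2) to 760 (without spcing1 replicate 1) genes for spcing1 against ing1, and 10 to 29 at least 2-fold higher and 18 to 69 lower. Without ada2a replicate 3, 150 genes were at least 2-fold higher in ada2aspc than in ada2a. Lower calls were 1105 for ada2aspc against ada2a without ada2a replicate 2, and 453 and 485 for spcing1 against spc without spc replicates 2 and 3. In ing1 rises outnumbered falls when any single Col-0 library, ing1 replicate 1 or ing1 replicate 2 was left out. The count for spcing1 against ing1 was 342, 252 and 233 without spcing1 replicate 3, ing1 replicate 2 and ing1 replicate 3. List calls went from 4 to 6 in ada2a and from 5 to 10 in sdrl (10 without sdrl replicate 1).

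The replicate block moved no count of genes by over 1.5 times (570 against 617 for spcing1 against ing1) and ended the call of 1 named gene, RHD6 in that contrast. Libraries of the same number did not deviate together (mean r -0.0007, against 0.0004 for other numbers), in 0 contrasts did every pair exceed 0.1, and in 0 did every library correlate best with its own number.

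The 6 libraries of a contrast make 10 splits, the real one counted among them, too few for a share under 0.05. In each contrast of genotypes the real split, 1 of 10, called the most genes, and the highest other split called between 0 and 3 genes, except 190 for ada2b against gcn5. As many lists as the real split were called by 3 of 10 splits in gcn5 (9 real, highest other 9), 2 in ada2b (11 and 11), 8 in ada2a (3 and 9), 5 in spc (6 and 9), 2 in ing1 (9 and 9), 5 in sdrl (6 and 10), 4 in eaf6 (9 and 10), 5 in ada2aspc (8 and 11) and 1 in spcing1 (9 and 8).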

Other observations

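The tests of the patterns in this part were all chosen after the results were seen. Across all 9 mutants 398 genes rose and 451 fell, where independent lists give 0 of either. These contrasts share the Col-0 libraries, which the independent lists leave out. Among the clock genes CCA1, LHY, PRR9 and RVE8 fell in all 9 mutants. CCA1 was at 1462 in Col-0 and between 22.1 in ada2b and 297 in sdrl. TOC1 rose in 8 mutants (6103 in Col-0 and 12780 in spc), as did LUX. ELF3 rose in 8 and fell in eaf6 (2985 in Col-0 and 2650 in eaf6), while GI and PRR7 fell in 8.

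In the 7 mutants other than gcn5 and ada2b, 115 genes rose at least 4-fold in every mutant, among them TCH4, TCH3, EXO and PHI-1. Different handling of the Col-0 libraries alone is argued against as the whole cause. The median log2 fold change of these genes was 0.52 in gcn5 (upper quartile 1) and 0.68 in ada2b (upper quartile 1.51). This argument holds only if gcn5 and ada2b did not themselves lower these genes, which was not tested. With genes chosen without a mutant in turn (115 to 132 genes), the mutant left out had a median of 2.71 to 3.27 and a lower quartile of at least 2.24, above the upper quartiles in gcn5 (at most 1.03) and ada2b (at most 1.9). Col-0 handling stays open for a part, as 48 of the genes passed as higher in gcn5 and 58 in ada2b, while 9 and 13 passed as lower. Loss of the same function as in gcn5 stays open, as a share of 0.417 of them passed as higher in gcn5, at a smaller size. Of all 21868 tested genes 3973 rose in gcn5. The genes were chosen by their rise against the same Col-0 libraries, which favours such calls. Harvest or handling of the 7 genotypes apart from Col-0, gcn5 and ada2b cannot be told apart from genotype, as no label gives a handling day (the lowest of the 7 medians, 2.81, is above 2 by the choice of genes and decides nothing). TCH4 and TCH3 are known to respond to touch, so handling may account for part of the rise.

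The fall of CCA1, LHY and PRR9 in all 9 mutants is not a matter of column scaling, since the smallest of the 27 changes was -1.16 after division by column totals and -1.25 before. A harvest of Col-0 at another hour may account for it and cannot be told apart from genotype, as no label gives the hour. An altered clock in the mutants stays open as a hypothesis that was not tested.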
